A study of Danio rerio with 35 samples.

How the data were processed

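The 35 libraries were made from zebrafish embryos at 2, 4, 6 and 8 hours post fertilization (hpf), across the maternal-to-zygotic transition, in which stored maternal RNA is cleared and the zygotic genome is switched on. Of these, 31 measured messenger RNA, from 5 embryos each, either as rRNA-depleted total RNA or as poly(A)+ RNA. The other 4 came from ribosome profiling, with 50 embryos per condition at the 64-cell stage, as footprints of 28 to 29 nt and as poly(A)+ input. Per the labels, embryos were injected at the 1-cell stage with morpholinos (MO, antisense oligonucleotides that block translation or splicing) or with alpha-amanitin, an RNA polymerase II inhibitor. Cycloheximide, which blocks translation, was added to the bath at the 32-cell stage. MZpou5f1 names embryos without maternal and zygotic pou5f1, a gene whose symbol in the annotation is pou5f3. The labels gave 32 groups, of which 2 had more than 1 library: WT total RNA at 6 hpf (n = 3) and Nanog+SoxB1 MO total RNA at 6 hpf (n = 2). Replicates are only labelled as separate samples, so p-values for total RNA at 6 hpf measure only the spread between these samples.

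The authors deposited exon and intron tables in RPKM (reads per kilobase of gene, scaled to library size), with 1 column per library and 3 decimals. The library total used for scaling was not given in the sources used here. The submitters' processing notes name CASAVA 1.8.2, Bowtie 0.12.9, TopHat2 2.0.7 and the genome build Zv9 (danRer7) without their order. The profiling table was named as RPKM, but its deposited values were in RPM (reads scaled to library size alone): every value was a whole multiple of a single step per column, within 0.1 read, and the step did not change with the transcript. Reads per transcript were recovered from that step. The exon table had 27997 entries, of which 846 joined overlapping genes and were left out of the tests, which left 27151. The intron table lost 626 of 24750 entries in the same way. Gene symbols were matched by identifier for 72.9% of exon, 75.5% of intron and 95.6% of profiling entries.

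The RPKM tables hold no read counts, so the absolute depth of those libraries is unknown. Relative depth was estimated from the smallest step of the values between library pairs, with WT total RNA at 4 hpf as the unit. It ran from 0.227 to 2.58, an 11.4-fold range. Shares of a gene set carry 95% Wilson intervals, which describe the set size only. Footprint values carry exact 95% Poisson intervals, and footprint ratios exact binomial (Clopper-Pearson) intervals. Both cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

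Fits used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend) on log2(RPKM + 0.5), without further scaling. They took genes at 1 RPKM or more in at least 2 libraries. Calls needed a Benjamini-Hochberg adjusted p under 0.05, two-sided. The 6 hpf fit took 11 total RNA libraries in group means, with 3 residual degrees of freedom and 16242 genes. In it, the 6 conditions with a single library were assumed to vary like the WT and Nanog+SoxB1 MO replicates. The 4 hpf fit took 8 total RNA libraries (Nanog MO, SoxB1 MO and MZpou5f1, each present or absent) in an additive model, with 4 residual degrees of freedom and 14498 genes. The rescue fit took WT, MZpou5f1 Nanog+SoxB1 MO (triple loss of function) and the latter with rescue mRNA at 4, 6 and 8 hpf, 9 libraries with stage as a block, 4 residual degrees of freedom and 16028 genes. Its libraries were total RNA at 4 hpf and poly(A)+ RNA at 6 and 8 hpf, so stage and RNA selection share that block and effects are averaged over both kinds of RNA. The 4 hpf and rescue fits held no replicate of a condition at a stage. Their residual spread, and so their SEs and p-values, also holds effects that are not additive or that differ between stages. Median spreads of a gene around the 6 hpf, 4 hpf and rescue fits were 0.28, 0.17 and 0.47 on the log2 scale. Single-library comparisons at 4 hpf and the profiling libraries were described by values without a test and without any replicate check.

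Gene sets at 4 hpf came from other libraries than the WT total RNA library they were compared with. The zygotic set (173 genes) had under 1 RPKM in WT at 2 hpf, at least 5 RPKM in WT poly(A)+ RNA at 4 hpf, and amanitin at least 4-fold below it. The first-wave set (53 genes, 45 of them in the zygotic set) had under 1 RPKM at 2 hpf, at least 5 RPKM in cycloheximide and at least 4-fold more than in amanitin. The intron set (691 genes) had at least 0.5 intron RPKM in cycloheximide, at least 4-fold above amanitin and above WT at 2 hpf. The maternal cleared set (2701 genes) had at least 5 RPKM at 2 hpf and a WT mean at 6 hpf at least 4-fold lower. A gene counted as reduced when it lay at least 4-fold below WT on the log2 scale, with 0.5 added to exon and 0.1 to intron RPKM. A maternal gene counted as retained at 2-fold or more above WT. The medians of the zygotic, first-wave and intron sets were ranked among 10000 random lists matched on expression, and those of the maternal set only where it was picked with 1 WT library at 6 hpf and compared with the others.

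The tested gene lists were pluripotency factors, dorsal organizer and Nodal, ventral BMP and Wnt, mesoderm with endoderm and FGF, neuroectoderm, enveloping layer and epidermis, maternal oocyte-derived genes, germ plasm, p53 response, heat shock and stress, cell cycle, maternal transcription factors, and ribosomal proteins. They were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, adjusted over the lists of a contrast. List members were counted as table entries with separate gene identifiers, and a few share a symbol. At 6 hpf 34 maternal transcription factor entries had 31 symbols, 73 ribosomal protein entries 70, 10 ventral entries 9 and 8 heat shock entries 7. Named genes followed a rule: the factors nanog, pou5f3, sox2, sox3, sox19a and sox19b everywhere; per limma contrast the 10 largest changes each way among called genes with a mean of at least 5 RPKM in the higher arm; per single-library comparison the 5 largest ratios each way at 10 RPKM or more; and per list the 4 largest changes. Clone-based names were skipped. The designs, sets, lists, this rule and the alternatives were chosen before the data were examined, except where stated.

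Alternatives were pseudocounts of 0.1 and 1, no filter, a filter at 5 RPKM, median-ratio and quantile scaling, leaving out each library, a replicate block, 4 and 6 hpf libraries together, and for sets other folds, pseudocounts and minimum levels. Procedures were tested on simulated data. For Nanog+SoxB1 MO against WT at 6 hpf, 68% of genes changed 2-fold and 97% of those changed 4-fold were recovered, with 5.17% false calls. For Nanog MO at 4 hpf 96% and 100% were recovered, and for the triple loss of function 3% and 46%. The contrasts with 1 library against 3 at 6 hpf were not simulated. Values were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and drawn with matplotlib 3.10.9.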

Results

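The series asks how maternal Nanog, SoxB1 and Pou5f1 contribute to switching on the zygotic genome. Messenger RNA was measured in 31 libraries and translation in 4. Total RNA at 4 hpf covered WT, amanitin, cycloheximide, U1U2 MO (against splicing RNAs), the 3 factors alone and combined, and a rescue, with 1 library each. Total RNA at 6 hpf covered WT (n = 3), Nanog+SoxB1 MO (n = 2) and 6 further conditions with 1 library each, and WT at 2 hpf had 1 library. Poly(A)+ RNA covered WT at 4, 6 and 8 hpf, and triple loss of function with and without rescue at 6 and 8 hpf. Relative to WT total RNA at 4 hpf, depth was lowest in Nanog+SoxB1 MO replicate 1 at 6 hpf (0.227) and highest in cycloheximide at 4 hpf (2.58). The profiling table held 399567 footprint reads in WT and 581218 in Nanog+SoxB1 MO, beside 1492629 and 1612899 input reads.

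WT embryos went from stored to newly made transcripts within this window. The mir-430 hairpin, precursor of a microRNA that clears maternal messages, was at 0.374 RPKM at 2 hpf and 1406 RPKM at 4 hpf. From 2 to 4 hpf, nnr went from 0 to 212 RPKM, her5 from 0 to 128 RPKM, klf17 from 0 to 77.6 RPKM and id1, a BMP target, from 0.513 to 154 RPKM. In poly(A)+ RNA from 4 to 6 hpf, the keratin krt5 went from 0.056 to 677 RPKM and krt92 from 0.594 to 480 RPKM, while maternal btg4 went from 120.5 to 0.839 RPKM, the claudin gene cldnd from 926 to 10.4 RPKM, and buc, organizer of the germ plasm, from 121 to 1.00 RPKM. From 6 to 8 hpf dlx3 went from 2.34 to 37.7 RPKM and hoxb1b from 0.447 to 11.4 RPKM. At 4 hpf poly(A)+ RNA held less mir-430 hairpin (2.91 RPKM) and histone h2ax2 (3.06 against 757 RPKM) than total RNA. Among the factors, nanog had 396 RPKM at 2 hpf and 598 RPKM at 4 hpf in total RNA, and 133 ± 52.6 RPKM at 6 hpf (SD, n = 3).

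At the 64-cell stage the factor transcripts carried many footprints, by level more than per unit of input. In WT, nanog carried 2415 RPM of footprints (95% interval 2284 to 2551), pou5f3 2074 RPM (1953 to 2201) and sox19b, the maternal SoxB1 gene, 2021 RPM (1902 to 2146). These were ranks 24, 30 and 33 among 8241 transcripts, and ranks 2, 3 and 4 among 34 maternal transcription factors, behind the beta-catenin gene ctnnb2 at 2593 RPM. RPM values are not divided by transcript length, so the ranks by level, the place behind ctnnb2 included, also depend on length. Footprints per input were 2.59 for nanog, 3.80 for pou5f3 and 8.68 for sox19b, against a median of 0.572, which were ranks 1041, 579 and 110 of 8241, and ranks 12, 7 and 2 of the 34 factors. Nanog+SoxB1 MO left 48.9 RPM on nanog, 2.02% of WT, with a ratio of 0.0142 to 0.0281, and 71.3 RPM on sox19b, 3.53% of WT, with a ratio of 0.0263 to 0.0464. Footprints on pou5f3, which neither morpholino targets, were 1.41 times WT (1.31 to 1.52). Its input rose alike, from 546 to 770 RPM, so its footprints per input were 3.80 in both. Input was not lower: nanog had 932 RPM in WT and 1674 RPM in the morphants, and sox19b 233 and 374 RPM. Among the largest ratios each way over all transcripts, ddx1 went from 38 reads to 0 (which allows up to 4.87 RPM), alg11 from 16 reads to 0 and nccrp1 from 15 reads to 0. In the other direction, mvb12a went from 0 to 23 reads and opa3 from 0 to 17 reads. Each condition had 1 footprint library, so no replicate check was possible.

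**Figure D1:**
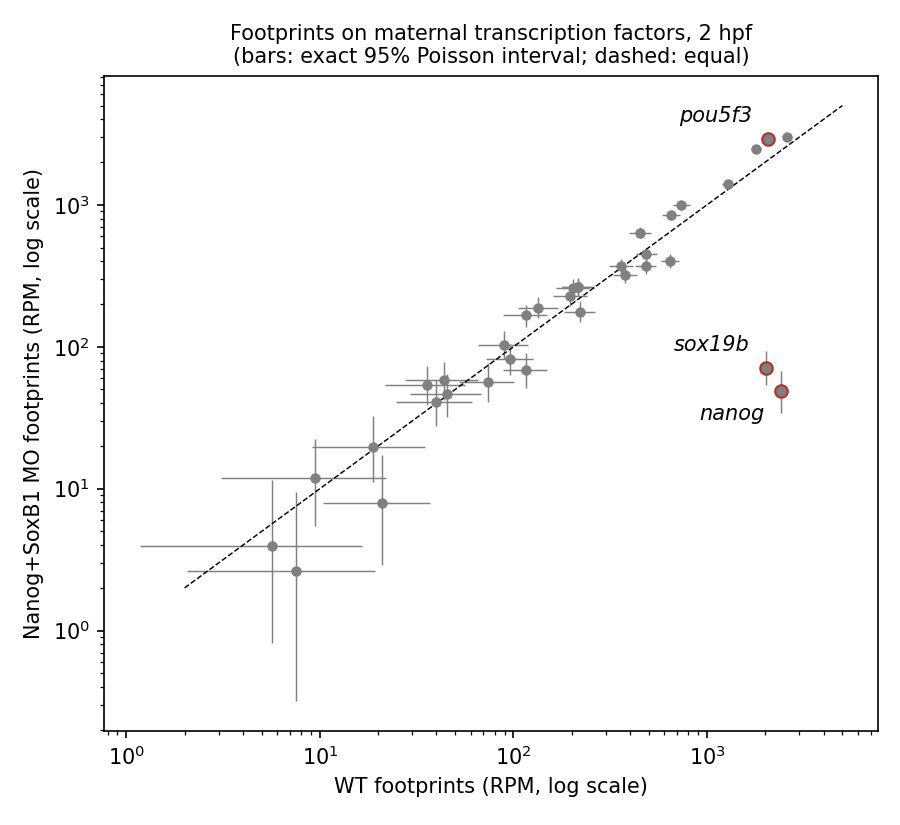
Footprints on 34 maternal transcription factor transcripts at 2 hpf in WT (x axis) and Nanog+SoxB1 MO (y axis), in RPM on log scales, with exact 95% Poisson intervals as bars and equality as a dashed line. nanog at 2415 and 48.9 RPM and sox19b at 2021 and 71.3 RPM lie far below the line, pou5f3 at 2074 and 2922 RPM above it.

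Inhibitors set the range for the zygotic response at 4 hpf. Under amanitin 155 of 173 zygotic genes were at least 4-fold below WT (89.6%, 95% Wilson interval 84.2 to 93.3), with a median log2 ratio of -4.77. The mir-430 hairpin was at 0.694 RPKM against 1406 RPKM in WT, nnr at 0.084 against 212 RPKM, her5 at 0.295 against 128 RPKM, and asb11 and vgll4l were listed at 0 against 95.2 and 92.9 RPKM. Cycloheximide kept 183 RPKM of mir-430 hairpin, while fthl28 was at 0.391 against 131 RPKM, krt18a.1, a keratin, at 0.330 against 53.8 RPKM, and vgll4l at 0.331 RPKM. Under it 127 zygotic genes (73.4%) and 32 of 53 first-wave genes (60.4%) were reduced. U1U2 MO reduced 63 zygotic genes (36.4%, and 59.0% counted at 2-fold). Among its largest ratios was grhl3, an epidermal regulator, at 0.814 against 33.8 RPKM, while gadd45g was at 30.6 against 7.36 RPKM. Amanitin helped to pick all 3 sets and cycloheximide the first-wave and intron sets, so these shares are not independent of that choice. In the same amanitin and cycloheximide libraries rflnb was at 84.8 and 101 RPKM against 0.144 RPKM in WT at 4 hpf and 52.6 RPKM at 2 hpf. For amanitin, ctsb was at 449 against 16 RPKM.

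Zygotic transcripts lay far below WT in Nanog MO alone and lower still in Nanog+SoxB1 MO. In Nanog MO at 4 hpf the mir-430 hairpin was at 15.0 RPKM, her5 at 1.35 RPKM, blf, a mesendoderm gene, at 2.90 against 189 RPKM, and cxcr4 at 1.24 against 80.7 RPKM. Nanog+SoxB1 MO left 0.681 RPKM of mir-430 hairpin, 0.322 RPKM of nnr and 0.806 RPKM of her5, with asb11 and vgll4l listed at 0. SoxB1 MO alone left mir-430 hairpin at 1688 RPKM, while vgll4l was at 0.102 RPKM, polr3gla at 0.934 against 14.9 RPKM and stm at 1.83 against 15.2 RPKM. The library labelled MZpou5f1 had vgll4l at 0.819 RPKM and klf17, a Kruppel-like factor of the enveloping layer, at 4.02 RPKM. MZpou5f1 SoxB1 MO had klf17 at 0.410 RPKM and ndrg1 at 0.235 against 59.4 RPKM, and ndrg1 was still at 0.083 RPKM with rescue mRNA in the triple background. The triple loss of function left mir-430 hairpin at 1.76 RPKM and asb11 at 0.302 RPKM, with nnr listed at 0.

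Of 173 zygotic genes, Nanog MO reduced 90 (52.0%, Wilson 44.6 to 59.3), SoxB1 MO 14 (8.09%, 4.88 to 13.1) and the library labelled MZpou5f1 37 (21.4%, 15.9 to 28.1). Nanog+SoxB1 MO and the triple loss of function each reduced 125 (72.3%, 65.2 to 78.4), MZpou5f1 Nanog MO 111 (64.2%) and MZpou5f1 SoxB1 MO 68 (39.3%). Rescue mRNA in the triple background left 19 reduced (11%, 7.15 to 16.5). Of the 125 genes reduced in the triple loss of function, 89 were also reduced in Nanog MO alone, 21 in no single loss, and 2 in no single or double loss. In the rescue, 77 of the 125 were less than 2-fold below WT and 117 were at least 2-fold above the triple loss of function. Of 53 first-wave genes, Nanog MO reduced 36 (67.9%), Nanog+SoxB1 MO 43 and the triple loss 43 (81.1% each), and SoxB1 MO 0, which allows up to 6.76%. In each of the 11 conditions, inhibitors and rescue included, the median ratio of the zygotic set lay below those of all 10000 matched random lists. The intron set did not do so throughout, with a percentile of 92.4 in cycloheximide and 34.3 in SoxB1 MO. For the zygotic set, amanitin had helped to pick the genes, and the rescue ranked as low as the losses. That rank alone therefore does not separate loss of a factor from other differences from WT. Counting 2-fold losses gave 27.7% for SoxB1 MO, 33.5% for the library labelled MZpou5f1 and 30.6% for the rescue, and differences between conditions were not tested, since each had 1 library. The library labelled MZpou5f1 also held pou5f3 at 28.0 RPKM, against 157 RPKM in WT and 0.088 to 1.87 RPKM in the other MZpou5f1 libraries at 4 hpf without rescue.

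**Figure D2:**
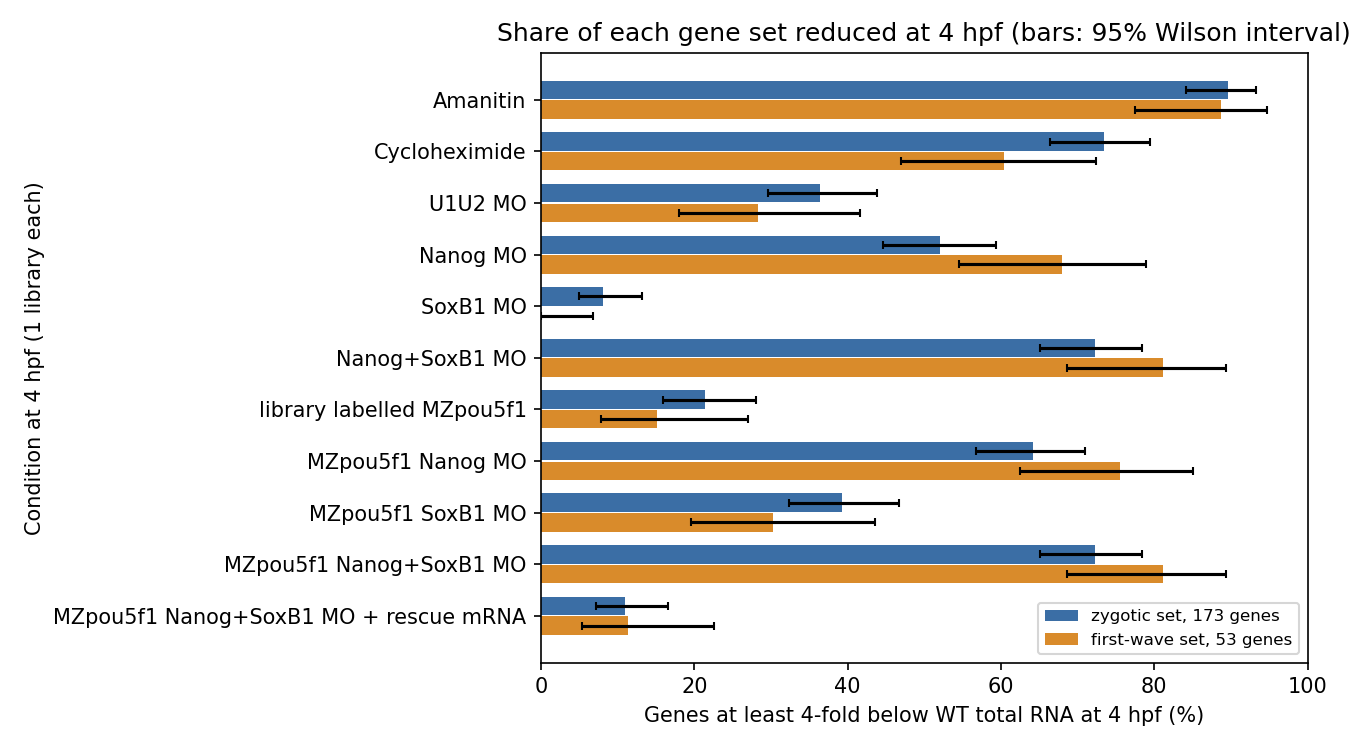
Share of the zygotic set (173 genes, blue) and first-wave set (53 genes, orange) at least 4-fold below WT total RNA at 4 hpf, in percent on the x axis, for each condition with 1 library (y axis), with bars for the 95% Wilson interval. Nanog+SoxB1 MO and the triple loss of function both reach 72.3% and 81.1%, SoxB1 MO 8.09% and 0%, and the rescue 11% and 11.3%.

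Introns gave a view of new transcription of genes whose message is also stored maternally. Among 554 such genes, amanitin reduced intron signal in 95.7% and exon signal in 7.22%. The set was picked for low introns in this amanitin library, so the intron share is not independent of that choice. Nanog MO reduced introns in 7.40%, Nanog+SoxB1 MO in 11.7% and the triple loss of function in 11.4%, against 2.71%, 3.61% and 3.97% for exons. Among the 137 genes without maternal message, the intron shares were 46%, 57.7% and 55.5%, and 9.49% in the rescue. Over the 691 genes, SoxB1 MO reduced 9 (1.30%) and the library labelled MZpou5f1 32 (4.63%). More of their introns lay at least 2-fold above WT than below it: 83 against 32 in SoxB1 MO and 223 against 58 in the library labelled MZpou5f1. This was no trait of the set, since its median log2 ratios of 0.364 and 0.675 lay below the medians of matched random intron lists, 0.377 and 0.737. The intron shares changed with the minimum level: with a minimum doubled to 1 RPKM, Nanog MO reduced 26.4% in place of 15.1%, Nanog+SoxB1 MO 37.4% in place of 20.8%, MZpou5f1 Nanog MO 29.7% in place of 17.9% and the triple loss 33.3% in place of 20.1%.

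Across the 8 libraries of the 4 hpf layout, Nanog MO lowered 339 genes and raised 775 of 14498. The mir-430 hairpin fell by 8.32 ± 0.53 on the log2 scale (SE, 4 libraries against 4), and so did her5 (-6.46 ± 0.15), blf (-5.49 ± 0.10), nnr (-5.31 ± 0.45), asb11 (-5.39 ± 0.42), cxcr4 (-5.00 ± 0.29) and apela (a ligand of the apelin receptor, -4.71 ± 0.26). The zygotic SoxB1 genes sox3 (-4.80 ± 0.16) and sox19a (-2.94 ± 0.42) fell, while maternal sox19b (-0.02 ± 0.06) and nanog itself (-0.28 ± 0.07) did not pass the test. Of 13 organizer and Nodal genes 5 fell, 7 adjusted over the list alone, among them chrd (-3.88 ± 0.15), the BMP antagonist, lft2 (-2.92 ± 0.23) and gsc (-2.50 ± 0.24). Of 12 mesoderm, endoderm and FGF genes 8 fell, 9 adjusted over the list alone, with mxtx2 at -4.21 ± 0.23 and tbx16 at -4.01 ± 0.26. Both lists kept their call (adjusted p = 0.0153 with an estimated correlation for each). Of 15 oocyte-derived genes 6 rose, 8 adjusted over the list alone, led by org (0.86 ± 0.11) and slbp2 (0.83 ± 0.07), with adjusted p = 0.195 with an estimated correlation. All 135 genes that changed at least 4-fold were lower. The count of 1114 was 665 without a filter, 3018 with 4 and 6 hpf libraries together and 576 in the 4 WT-background libraries alone, an alternative chosen after the data were seen. Leaving out 1 library gave 594 (SoxB1 MO), 505 (Nanog+SoxB1 MO), 633 (the library labelled MZpou5f1), 465 (MZpou5f1 Nanog MO) and 517 (MZpou5f1 Nanog+SoxB1 MO).

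The MZpou5f1 background at 4 hpf went with 6113 called genes, 3500 higher and 2613 lower. The 21 calls for SoxB1 MO fell to 1 or 0 with any library left out. Among MZpou5f1 changes, pou5f3 fell by 5.87 ± 0.80 on the log2 scale, as did ndrg1 (-6.01 ± 0.42), cyp2x7 (-5.88 ± 0.30) and klf17 (-4.50 ± 0.54), while rflnb rose by 7.27 ± 0.17, neu3 by 5.21 ± 0.14, ctsb by 4.27 ± 0.07 and upk2 by 4.61 ± 0.17. In the enveloping layer list 3 of 13 fell, klf17 and klf2b (-2.59 ± 0.58) among them, and 1 rose, epcam, an adhesion molecule, by 1.06 ± 0.08. In the dorsal organizer list 4 of 13 rose, with lft1 at 0.96 ± 0.21 and noto at 0.90 ± 0.10, and 2 fell, with foxd3 at -1.79 ± 0.53. These counts were the same adjusted over the list alone, and neither list passed camera (adjusted p = 0.631 for each), while the organizer list passed fry, upwards (adjusted p = 0.0382). For rflnb, neu3 and ctsb the genotype coincided with a difference also seen between libraries of WT embryos: neu3 had 0.054 RPKM in untreated WT at 4 hpf and 19.3 RPKM under cycloheximide, ctsb had 16 RPKM in total RNA of WT at 4 hpf and 344 RPKM in its poly(A)+ RNA, and rflnb 0.144 and 20.3 RPKM. These pairs of libraries also differ in treatment (neu3) or in RNA type (ctsb and rflnb), which was not separated from a difference between embryos. Rescue mRNA in the triple background (1 library at 4 hpf) left ndrg1 at 0.083 against 59.4 RPKM in WT and upk2 at 27.3 against 0.168 RPKM. There rflnb (123 RPKM) and neu3 (23.5 RPKM) stayed high as well. For these genes, loss of pou5f3 cannot be told from another difference between the embryos. SoxB1 MO gave 21 called genes, with ackr3 at -1.65 ± 0.18, noto at -0.94 ± 0.10 and birc5b at 0.80 ± 0.09. Another split of the same libraries gave 160, but it holds treatment effects and so decides nothing about SoxB1 MO. With any of the 8 libraries left out, limma called 1 gene without SoxB1 MO or without MZpou5f1 SoxB1 MO and 0 without WT, Nanog MO, Nanog+SoxB1 MO, the library labelled MZpou5f1, MZpou5f1 Nanog MO or MZpou5f1 Nanog+SoxB1 MO, while 2491 genes had an unadjusted p under 0.05 with all 8. The count for SoxB1 MO was 0 without a filter, 50 with a filter at 5 RPKM, 39 with 4 and 6 hpf libraries together, and 359 in the 4 WT-background libraries alone.

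At 6 hpf, in the only comparison with replicates on both sides, Nanog+SoxB1 MO embryos had far less of several zygotic transcripts, zygotic SoxB1 genes among them. The largest losses were stm at -9.46 ± 0.12 on the log2 scale (SE, n = 2 against 3; 0.135 against 446 RPKM), mttp, a lipid transfer protein of the yolk syncytial layer, at -7.63 ± 0.25, the cathepsin ctsll at -7.36 ± 0.26, nr0b2 at -7.34 ± 0.29 and polr3gla at -7.25 ± 0.17. Zygotic sox2 (-6.44 ± 0.30) and sox3 (-6.40 ± 0.18) fell, sox19a fell by 2.15 ± 0.10 and pou5f3 by 1.95 ± 0.12, while sox19b rose by 3.30 ± 0.10 and nanog by 1.75 ± 0.28, a call that was lost without Nanog+SoxB1 MO replicate 1. The largest gains were ptges3l at 5.18 ± 0.50, septin3 at 5.06 ± 0.31, sparc, a matrix protein, at 4.71 ± 0.27, acadl at 4.26 ± 0.43 and atf5a at 4.04 ± 0.23. Of 16242 genes 7190 were called, 4914 higher and 2276 lower. At least 4-fold changes numbered 722 up and 536 down.

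In Nanog+SoxB1 MO at 6 hpf most measured genes of the lists for germ layers and their patterning fell. These list calls were lost in camera, with adjusted p = 0.12 with an estimated correlation for the ventral, neuroectoderm, mesoderm and organizer lists and adjusted p = 0.181 with an estimated correlation for the enveloping layer list. All 10 ventral BMP and Wnt entries (9 symbols) fell, with eve1 at -6.99 ± 0.22 and bmp7a at -5.26 ± 0.20, and all 8 neuroectoderm genes, with her5 at -4.19 ± 0.29. Of 17 mesoderm, endoderm and FGF genes 12 fell, with dusp6, a feedback inhibitor of FGF signalling, at -5.04 ± 0.24 and mxtx1 at -4.38 ± 0.21, and of 14 organizer genes 8, with foxd3 at -4.13 ± 0.34 and gsc at -2.75 ± 0.20; these 4 counts were the same adjusted over the list alone. Of 17 enveloping layer and epidermis genes 12 fell, 14 adjusted over the list alone, with krt5 at -5.84 ± 0.47 and krt17 at -5.21 ± 0.26. Ribosomal proteins were lower by small amounts, 67 of 73 entries with 70 symbols (69 adjusted over the list alone), with a median of -0.63 and rps27.1 at -1.04 ± 0.09. In the other direction 13 of 15 oocyte-derived genes rose (14 adjusted over the list alone), with slbp2 at 2.93 ± 0.23 and btg4 at 2.83 ± 0.14, and 8 of 10 germ plasm genes (8 adjusted over the list alone), with buc at 3.64 ± 0.23 and tdrd6 at 3.40 ± 0.13. The calls of these 3 lists were lost as well, with adjusted p = 0.12 with an estimated correlation for the ribosomal list and adjusted p = 0.181 with an estimated correlation for the oocyte and germ plasm lists.

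Stress and regulator lists moved in parts. Of 11 p53 response genes 8 rose, 10 adjusted over the list alone, with sesn1 at 3.88 ± 0.35, cdkn1a, a cell cycle inhibitor, at 3.24 ± 0.46 and bbc3, a pro-apoptotic gene, at 2.81 ± 0.44 (adjusted p = 0.443 with an estimated correlation). At 4 hpf the same morphants had gadd45a at 47.2 against 3.00 RPKM, phlda3 at 14.3 against 1.19 RPKM and cdkn1a at 32.3 against 4.76 RPKM, in 1 library each. In the heat shock list 4 of 8 entries (7 symbols) rose and 2 fell, the same adjusted over the list alone, with hspa8 at 2.60 ± 0.62 and hspb1 at -6.00 ± 0.29 (adjusted p = 0.723 with an estimated correlation). In the cell cycle list 2 of 10 rose and 3 fell, the same adjusted over the list alone, with plk1 at 0.64 ± 0.10 and ccnb3 at -1.09 ± 0.10, and the list median of 0.10 was -0.23 after median-ratio scaling (adjusted p = 0.443 with an estimated correlation, downwards). Of 34 maternal transcription factor entries (31 symbols) 7 rose and 14 fell, 8 and 15 adjusted over the list alone, with eomes at 2.70 ± 0.23, mych at -2.94 ± 0.14 and foxh1 at -2.40 ± 0.11 (adjusted p = 0.181 with an estimated correlation). Of 6 pluripotency factors 2 rose and 4 fell, adjusted over the list alone as well (adjusted p = 0.150 with an estimated correlation). The median of all genes lay at 0.30 log2 above WT and at 0.01 after median-ratio scaling, where 52.0% of called genes were lower in place of 31.7%, or 46.5% after quantile scaling. Without Nanog+SoxB1 MO replicate 1 the count was 3743, and without replicate 2 it was 3876.

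**Figure D3:**
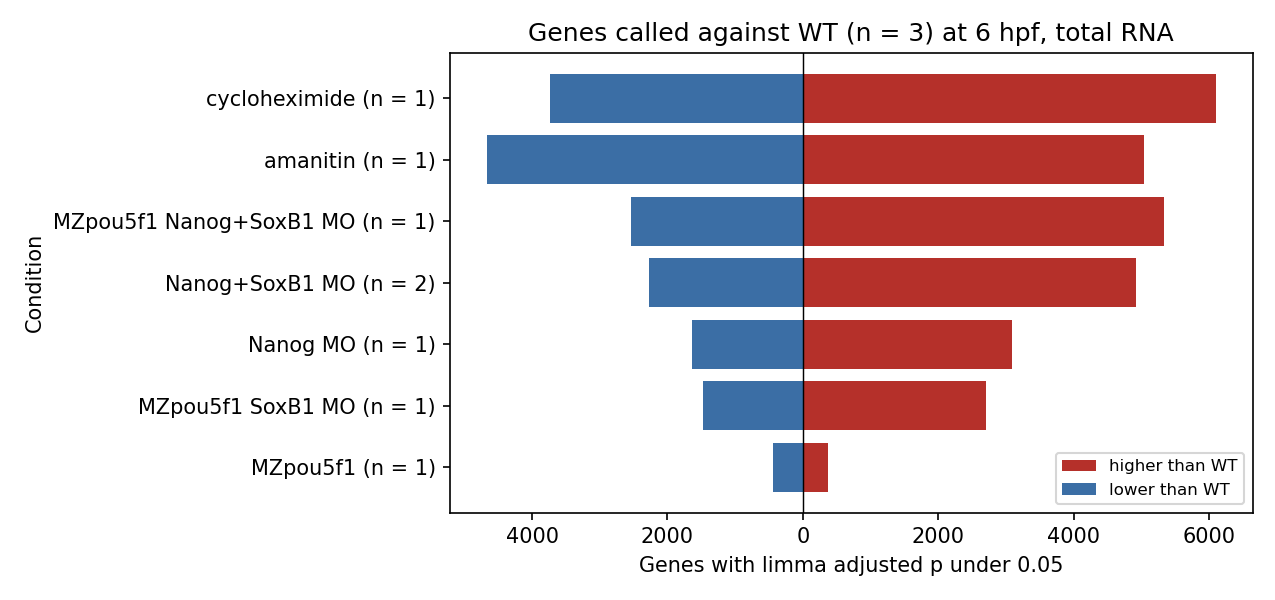
Genes called by limma against WT (n = 3) in total RNA at 6 hpf, as counts on the x axis to the right (higher, red) and left (lower, blue), for each condition on the y axis (n = 2 for Nanog+SoxB1 MO, 1 library for the others). Counts run from 806 in MZpou5f1 to 9826 in cycloheximide, on values without further scaling.

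Nanog MO alone at 6 hpf lowered most genes of the ventral and mesoderm lists and raised most oocyte-derived and germ plasm genes. Maternal genes did not all rise, as the maternal transcription factor list had a median log2 change of -0.34. The largest losses were afp4 at -6.97 ± 0.34 on the log2 scale (SE, 1 library against 3), ctsll at -6.80 ± 0.33, cxcr4 at -6.66 ± 0.33, nr0b2 at -5.78 ± 0.37 and hnf4a, a nuclear receptor of endodermal lineages, at -5.72 ± 0.38. Of the factors sox3 fell by 4.08 ± 0.23 and sox2 by 2.37 ± 0.38, while nanog rose by 2.38 ± 0.36. Of 10 ventral entries 9 fell, with eve1 at -4.97 ± 0.27 and bmp4 at -3.30 ± 0.35, and of 17 mesoderm genes 11 fell and 1 rose (13 and 1 adjusted over the list alone), with mespaa at -4.54 ± 0.59 (adjusted p = 0.184 with an estimated correlation for both). Germ plasm genes rose in 8 of 10 cases (9 adjusted over the list alone), with buc at 3.58 ± 0.30, and oocyte-derived genes in 13 of 15, with slbp2 at 3.25 ± 0.30 (adjusted p = 0.184 with an estimated correlation for both). Of 16242 genes 4724 were called, 3088 higher and 1636 lower. The median of all genes was 0.21, and -0.04 after median-ratio scaling, where 56.0% of called genes were lower in place of 34.6%, or 48.0% after quantile scaling. Without Nanog+SoxB1 MO replicate 1 the count was 3136 and without replicate 2 it was 3124.

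In MZpou5f1 embryos at 6 hpf fewer genes passed the test than in the morphants. Their pou5f3 fell by 6.50 ± 0.15 on the log2 scale (SE, 1 library against 3; 4.32 against 438 ± 47.4 RPKM, SD), as did sox2 (-6.97 ± 0.38), sult6b1 (-7.13 ± 0.28), slc2a12 (-5.62 ± 0.22) and vgll4l (-5.18 ± 0.33), while upk2 rose by 4.93 ± 0.31, flt3 by 3.92 ± 0.34 and dmbx2 by 3.87 ± 0.38. Values for nanog (0.21 ± 0.36), sox3 (-0.32 ± 0.23) and sox19a (0.00 ± 0.12) did not pass the test. Of 10 ventral entries 5 fell, 7 adjusted over the list alone, with bmp4 at -4.38 ± 0.35 and cdx4 at -3.37 ± 0.43 (adjusted p = 0.469 with an estimated correlation). In the enveloping layer list, where 3 of 17 fell (4 adjusted over the list alone) and 1 rose, klf2b (-3.72 ± 0.32), tfap2c (-3.41 ± 0.30) and klf17 (-3.16 ± 0.35) fell and epcam rose by 1.88 ± 0.24 (adjusted p = 0.484 with an estimated correlation). In the organizer list foxd3 (-3.28 ± 0.42) and tdgf1 (-1.09 ± 0.20) fell. The 806 calls (363 higher, 443 lower) turned on single libraries: 283, 268 and 1327 without WT replicates 1, 2 and 3, and 126 and 94 without Nanog+SoxB1 MO replicates 1 and 2. After median-ratio scaling 71.2% of called genes were lower in place of 55.0%, with the median of all genes at 0.00 in place of 0.15. Without a filter on low values the balance turned, with 858 higher and 301 lower.

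More genes passed the test when SoxB1 MO, and then Nanog MO, was added to MZpou5f1, though differences between these conditions were not tested. MZpou5f1 SoxB1 MO lowered 1469 and raised 2696 genes: rabgap1l2 at -7.39 ± 0.30, sox2 at -6.56 ± 0.38 and polr3gla at -6.23 ± 0.21 fell, while upk2 (4.83 ± 0.31) and tbx5, a heart and fin regulator, (4.23 ± 0.43) rose. There, 8 of 10 ventral entries fell, with bmp4 at -5.53 ± 0.35, and 13 of 17 enveloping layer genes, with klf2b at -4.93 ± 0.32, the same adjusted over the list alone (adjusted p = 0.255 with an estimated correlation for both). MZpou5f1 Nanog+SoxB1 MO lowered 2544 and raised 5326 genes: stm fell by 9.54 ± 0.16, as did ctsll (-8.71 ± 0.33), krt92 (-8.56 ± 0.34), nnr (-8.55 ± 0.42) and sox3 (-6.45 ± 0.23), while sesn1 rose by 4.97 ± 0.44 and btg4 by 4.59 ± 0.18. In it 16 of 17 mesoderm genes fell, with mxtx1 at -6.63 ± 0.26 (adjusted p = 0.111 with an estimated correlation), 15 of 17 enveloping layer genes (0.156 likewise) and 10 of 10 ventral entries, with eve1 at -7.34 ± 0.27 (0.127 likewise), all the same adjusted over the list alone. Germ plasm gene tdrd6 rose by 3.77 ± 0.16, among 6 of 10 (7 adjusted over the list alone, adjusted p = 0.255 with an estimated correlation). Among 4165 and 7870 calls, lower genes made 35.3% and 32.3%, and 61.7% and 55.7% after median-ratio scaling, which moved the median of all genes from 0.25 to -0.03 and from 0.40 to -0.03. The first count was 2615 without WT replicate 2, and 2182 and 2153 without Nanog+SoxB1 MO replicates 1 and 2.

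With transcription or translation blocked until 6 hpf, most genes of the mesoderm and enveloping layer lists lay below WT and most oocyte-derived genes above it, while maternal transcription factors went both ways. Amanitin lowered krt18a.1 (-9.44 ± 0.13 on the log2 scale, SE, 1 library against 3), apoc1 (an apolipoprotein, -9.24 ± 0.20), asb11 (-8.85 ± 0.14) and krt4 (-8.72 ± 0.17), and sox19a and sox3 fell by 7.67 ± 0.12 and 7.92 ± 0.23, while niban2 rose by 4.87 ± 0.19 and acadl by 4.92 ± 0.55. All 17 mesoderm genes (adjusted p = 0.126 with an estimated correlation) and 16 of 17 enveloping layer genes fell (adjusted p = 0.189 with an estimated correlation), with tbx16 at -7.53 ± 0.17, as did 68 of 73 ribosomal protein entries (70 symbols), with a median of -1.51 (adjusted p = 0.126 with an estimated correlation). In the p53 list, which moved both ways, gadd45a (-3.53 ± 0.42) and cdkn1a (-3.44 ± 0.59) fell. Cycloheximide raised btg4 by 6.84 ± 0.18 and maternal zar1l by 5.48 ± 0.35, lowered krt4 (-10.46 ± 0.17) and apoc1 (-8.99 ± 0.20), and lowered sox19a (-2.21 ± 0.12), with sox2 listed at 0. There, 15 of 17 mesoderm genes fell and 1 rose (adjusted p = 0.16 with an estimated correlation), and 4 of 8 neuroectoderm genes fell and 2 rose (0.394 likewise). Oocyte-derived genes rose in 14 of 15 cases under amanitin (adjusted p = 0.189 with an estimated correlation) and 13 of 15 under cycloheximide (adjusted p = 0.208 with an estimated correlation), with cldnd at 5.23 ± 0.48 in the latter. These list counts under amanitin and cycloheximide were the same adjusted over the list alone. Of 34 maternal transcription factor entries (31 symbols) 18 fell and 5 rose under cycloheximide (18 and 7 adjusted over the list alone, adjusted p = 0.208 with an estimated correlation), and 14 fell and 11 rose under amanitin, the same adjusted over the list alone. Ribosomal protein entries were lower under cycloheximide as well, in 69 of 73 cases (70 adjusted over the list alone, adjusted p = 0.16 with an estimated correlation). Calls numbered 9708 (4669 lower) under amanitin and 9826 (3728 lower) under cycloheximide. Median-ratio scaling moved the share of lower genes from 48.1% to 62.8% and from 37.9% to 54.9%, and the median of all genes from 0.11 to -0.23 and from 0.35 to -0.13.

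Maternal messages that WT embryos cleared by 6 hpf lay above WT in each of the 7 other conditions. Of 2701 such genes, 65.8% were at least 2-fold above WT in Nanog MO, 61.9% in Nanog+SoxB1 MO, 48.0% in MZpou5f1 SoxB1 MO, 13.0% in MZpou5f1 and 83.7% in MZpou5f1 Nanog+SoxB1 MO. The inhibitors gave 67.2% for amanitin and 92.5% for cycloheximide. btg4, a member of the antiproliferative BTG family made in eggs, had 4.97 ± 0.66 RPKM in WT (SD, n = 3) and 38.2 ± 1.8 RPKM in Nanog+SoxB1 MO (SD, n = 2), and buc had 12.7 ± 3.70 and 160 ± 15.0 RPKM. Median log2 ratios were 1.22 in Nanog+SoxB1 MO, 0.50 in MZpou5f1 and 1.76 in MZpou5f1 Nanog+SoxB1 MO. The set was picked with the WT mean at 6 hpf, which favours values above WT, and differences between conditions were not tested. It was therefore also picked with 1 WT library and compared with the mean of the other WT libraries, each in turn, an alternative chosen after the data were seen. The shares were then 61.2 to 65.8% in Nanog MO, 57.3 to 62.2% in Nanog+SoxB1 MO, 41.1 to 50.2% in MZpou5f1 SoxB1 MO, 78.9 to 82.2% in MZpou5f1 Nanog+SoxB1 MO, 63.8 to 65.9% in amanitin and 89.9 to 91.8% in cycloheximide. MZpou5f1 had 10%, 12.7% and 18% with the set picked from WT replicates 1, 2 and 3. The higher share between the held-out WT libraries of the same turn was 5.89%, 9.59% and 3.69%. The MZpou5f1 medians of 0.405 to 0.505 lay above those between WT libraries (up to 0.265) and those of matched random lists (0.081 to 0.114). At 4-fold in place of 2-fold the shares were 16.6% for Nanog+SoxB1 MO, 0.56% for MZpou5f1 and 37.4% for MZpou5f1 Nanog+SoxB1 MO.

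**Figure D4:**
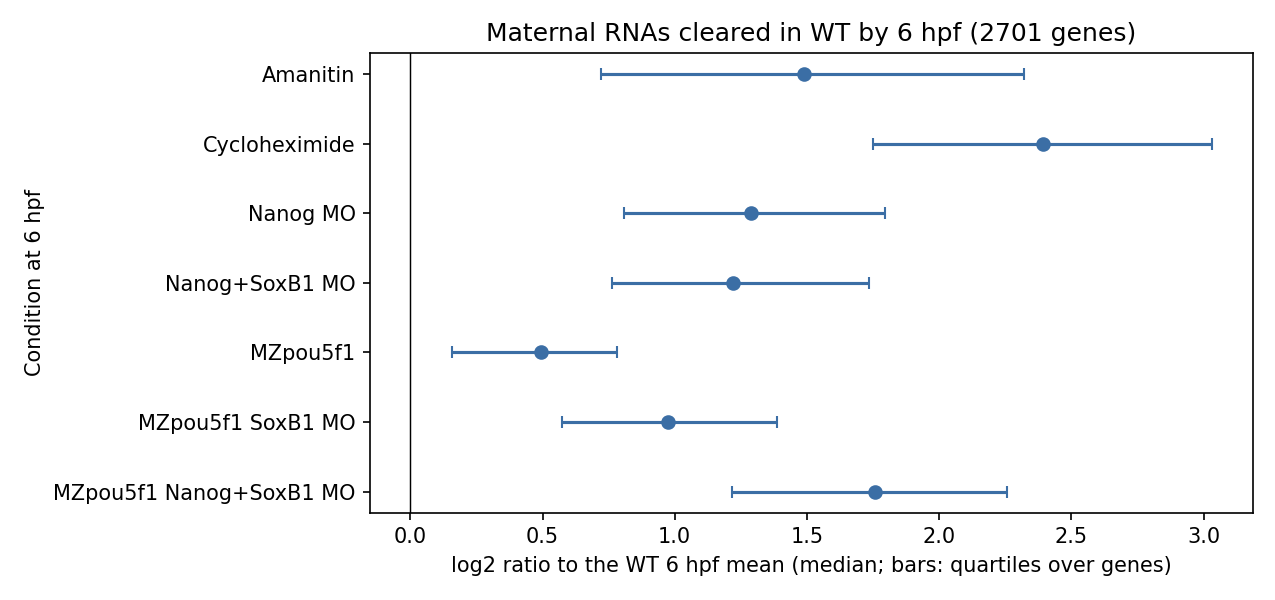
Log2 ratio to the WT mean at 6 hpf of 2701 maternal messages cleared in WT (x axis) for each condition (y axis), as the median over genes with bars for the quartiles over genes. Medians run from 0.50 in MZpou5f1 to 2.39 in cycloheximide, all above 0.

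Rescue mRNA raised a part of the genes that fell in the triple loss of function between 4 and 8 hpf. In the triple loss of function klf17 fell by 6.26 ± 0.26 on the log2 scale (SE, 3 libraries against 3), as did nnr (-7.02 ± 0.56), apoeb (an apolipoprotein of the yolk syncytial layer, -5.96 ± 0.28), pou5f3 (-7.83 ± 0.44) and the BMP family gene admp (-5.31 ± 0.43). Against it, the rescue raised klf17 by 6.52 ± 0.26, nnr by 6.40 ± 0.56, pou5f3 by 8.98 ± 0.44, sox3 by 6.56 ± 0.56, sox19a by 5.96 ± 0.68 and foxd3 by 5.10 ± 0.59. The factor values include any injected message, whose makeup is not given in the sources used here: at 4 hpf the rescue held nanog at 2395 RPKM and sox2 at 443 RPKM against 0.275 RPKM in WT. Of 17 enveloping layer genes 11 fell and 1 rose in the triple loss of function, 14 and 1 adjusted over the list alone, a list that kept its call (adjusted p = 0.0175 with an estimated correlation), and 5 rose in the rescue, 14 higher and 1 lower adjusted over the list alone (0.00823 likewise), with klf2b at 4.65 ± 0.32 and tfap2a at 3.59 ± 0.45. Of 18 mesoderm genes 2 rose in the rescue, 12 adjusted over the list alone, with dusp6 at 4.45 ± 0.26 (0.0276 likewise). Oocyte-derived btg4 rose by 4.15 ± 0.64 in the triple loss, a call lost without either WT or triple loss library at 6 or 8 hpf.

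In counts, the triple loss lowered 744 and raised 1853 of 16028 genes, and the rescue raised 97 and lowered 1 against it. Of the 744 lowered genes 83 rose in the rescue, against 4.50 for independent lists, and their median went from -2.004 in the triple loss to -0.75 in the rescue, both against WT. Of the 1853 raised genes 1 fell, against 0.116 for independent lists, and their median went from 1.77 to 1.23. Both contrasts share the triple loss libraries, which alone makes changes opposite: the correlation across genes was -0.71, against -0.50 in simulated data without change, the covariance -0.63 against -0.10, and 74.1% of genes had opposite signs, against 66.8%. The count of 2597 for the triple loss was 315 without a filter (150 higher and 165 lower), 1275 after quantile scaling and 10402 without the 4 hpf stage, which also leaves out its total RNA, an alternative chosen after the data were seen. It was 7654, 7886 and 553 without the WT, triple loss or rescue library at 4 hpf, 46, 53 and 154 without those at 6 hpf, and 68, 69 and 215 without those at 8 hpf. With the WT and triple loss libraries alone, the triple loss count was 18. With the rescue and triple loss libraries alone, the rescue count was 55. Both fits were made after the data were seen and leave fewer residual degrees of freedom. The 98 calls of the rescue were 61 without a filter and 4834 without the 4 hpf stage. They were 215 without WT at 4 hpf, 2414 without the triple loss at 4 hpf, 63, 37 and 33 without WT, triple loss or rescue at 6 hpf, and 50 and 27 without triple loss or rescue at 8 hpf. Median-ratio scaling moved the share of lower genes in the triple loss from 28.6% to 51.7%, or 55.7% with quantile scaling, and the median of all genes from 0.45 to 0.13. For the rescue against the triple loss it moved the median of all genes from -0.11 to 0.00.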

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

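All tests in this part, including the counts over other splits of the libraries, were chosen after the results were seen. Among the entries that join overlapping genes, and so were left out of every comparison, 8 lay at 5 RPKM or more in WT at 4 hpf and at least 4-fold above amanitin, which is a signal in data outside the main measurement. In all, 182 of these entries reached 5 RPKM in WT.

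A few transcripts parted the libraries without regard to treatment. rflnb was at 0.144 RPKM in WT total RNA at 4 hpf, 0.058 RPKM in Nanog MO and 0.068 RPKM in WT replicate 3 at 6 hpf, but at 84.8 RPKM in amanitin at 4 hpf and 3.27 and 3.72 RPKM in WT replicates 1 and 2 at 6 hpf. Such a split could come from different embryo batches or parental fish. Among 8 genes defined from WT at 2 and 4 hpf, WT replicate 3 at 6 hpf lay at a median log2 ratio of -1.07 to the other replicates (0.22 and 0.31 when replicate 1 or 2 was singled out). Over the 6 genes left without rflnb and ctsb, which had already been seen, it lay at -0.61. Genes at least 8-fold apart from both other replicates numbered 4 for replicate 3, with 3 and 5 for replicates 1 and 2. At 4 hpf the genotype and this split cannot be told apart, because all MZpou5f1 libraries lay on 1 side of it, and differences between parents stay open, untested. At 6 hpf Nanog MO lay on the side of WT replicate 3 for rflnb (0.073 RPKM) and ctsb (10.9 RPKM). In WT replicates 1, 2 and 3, ctsb was at 302, 282 and 69.8 RPKM. Whether other differences of Nanog MO from WT at 6 hpf follow this split was not tested.

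The library labelled MZpou5f1 at 4 hpf held pou5f3 at 28.0 RPKM together with transcripts of later embryos. Over 166 genes picked for at most 0.5 RPKM in the other 7 libraries of the layout and at least 10 RPKM in a 6 hpf library, its median was 0.682 RPKM, with 67 above 1 RPKM. Collection at a later stage stays undecided. The log2 ratio of the library to MZpou5f1 at 6 hpf had an SD of 2.80, above the SD of 1.18 against Nanog+SoxB1 MO replicate 2 at 6 hpf. But embryos between 4 and 6 hpf need not hold these genes at an equal share of their 6 hpf level. The 166 genes could also be picked through any 6 hpf library, which widens the ratios to libraries that lack some of them. RNA or reads from a 6 hpf library of another condition stay a candidate source: the library held these genes at a median of 28.3% and 34.1% of their level in Nanog+SoxB1 MO replicates 1 and 2, and pou5f3 at 24.6% and 25.3%. A share of embryos as in WT is argued against for both parts, though the median of 0.682 RPKM had not reached a bound of 1 RPKM set earlier. WT poly(A)+ RNA at 4 hpf, which took no part in picking the 166 genes, held 3 of them above 1 RPKM (upper 95% limit 5.19%), against 67 in the library (lower limit 32.8%). The pou5f3 level came to 17.8% of that in WT total RNA. Of 5870 other genes at 10 RPKM or more in both WT libraries at 4 hpf, 14 lay under 50% of that share, among them vgll4l (0.819 of 92.9 RPKM) and klf17 (4.02 of 77.6 RPKM), named after their values were seen. By the same rule 0, 0 and 1 genes lay as low when a WT replicate at 6 hpf was set against the others (upper 95% limit 5.57). A smaller share of such embryos beside another source, and embryos of other genotypes, were not tested.

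In the 4 hpf layout, 1 of 33 splits of the 8 libraries gave as many genes for Nanog MO (1114, the real split, highest other 0), and 1 of 33 for MZpou5f1 (6113, highest other 0). This is the lowest share that 33 splits can give, which argues against chance without excluding it. The other splits leave the tested factor out of the model, so its effect adds to their spread and their counts of 0 do not measure noise. For MZpou5f1, the genotype cannot be told apart from the split of libraries described above. For SoxB1 MO 2 of 33 splits gave 21 or more, the real split included. The highest of them, with 160 genes, set WT, Nanog MO, the library labelled MZpou5f1 and MZpou5f1 SoxB1 MO against the rest. That split parts the wild-type libraries by SoxB1 MO and the MZpou5f1 libraries by Nanog MO. It therefore holds treatment effects, and is evidence neither of chance nor of another structure of the samples. The splits thus leave chance undecided for SoxB1 MO. With only the 6 libraries of the groups compared, the triple loss of function gave 18 genes and the rescue 55. For each, 1 of 10 splits gave as many (the real split, highest other 0), and 10 splits are too few for a share under 0.05.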

How the results depend on the processing

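Calls and shares were repeated under each alternative, and 3 of these were chosen after the data were seen: the 4 WT-background libraries alone, the rescue series without its 4 hpf stage, and the maternal set picked with 1 WT library. No named gene that was called in the main fit changed direction, a weak check, since most were picked as the largest called changes. Over named genes and alternatives, 4422 values kept their side of the threshold, 483 lost it and 27 gained it. With 1 library left out, SoxB1 MO at 4 hpf lost it in 126 values and kept it in 42, and the rescue against WT lost it in 122 and kept it in 78. Counts at 6 hpf stayed within 1.5 times under every pseudocount, filter and scaling, as did MZpou5f1 at 4 hpf. Nanog+SoxB1 MO at 6 hpf gave 7259 genes in its 5 libraries alone and 7858 with replicate number as a block. The numbers do not pair the samples, with correlations of 0.0856 and 0.0625 between equal numbers. Scaling could not change footprint ranks within the WT library. A higher input minimum takes out transcripts, but could not move nanog, pou5f3 and sox19b among the 34 factors, where only ctnnb2 lay above, with 418 RPM of input. Those alternatives therefore decide nothing about the ranks among the factors.

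Without a filter, Nanog MO at 4 hpf gave 665 genes, SoxB1 MO 0 by limma, the triple loss of function 315 and the rescue 61. A filter at 5 RPKM gave 50 for SoxB1 MO. Quantile scaling gave 1275 for the triple loss. The 4 and 6 hpf libraries together gave 3018 for Nanog MO and 39 for SoxB1 MO. The 4 WT-background libraries gave 576 and 359. Without the 4 hpf stage, the triple loss gave 10402 and the rescue 4834. In the fits to 6 libraries made for the splits above, they gave 18 and 55. Where fewer libraries or more genes were tested, construction bears on the count, and otherwise the cause was not tested.

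Leaving out 1 library gave 8819 to 10053 genes for amanitin at 6 hpf, 8958 to 10091 for cycloheximide, 94 to 1327 for MZpou5f1, 6697 to 8165 for MZpou5f1 Nanog+SoxB1 MO, 2153 to 4827 for MZpou5f1 SoxB1 MO, 3124 to 5722 for Nanog MO and 3743 to 7335 for Nanog+SoxB1 MO. At 4 hpf it gave 465 to 1274 for Nanog MO, 0 to 1 for SoxB1 MO and 4756 to 5855 for MZpou5f1. In the rescue series it gave 46 to 7886 for the triple loss and 27 to 2414 for the rescue.

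Zygotic genes counted at 2-fold were 93.6% in amanitin, 89.0% in cycloheximide, 59.0% in U1U2 MO, 66.5% in Nanog MO, 27.7% in SoxB1 MO, 81.5% in Nanog+SoxB1 MO, 33.5% in the library labelled MZpou5f1, 78.6% in MZpou5f1 Nanog MO, 53.8% in MZpou5f1 SoxB1 MO, 83.2% in the triple loss and 30.6% in the rescue, since a lower fold counts more genes. With the minimum level doubled they were 98.2% in amanitin, 80.6% in cycloheximide, 81.5% in Nanog+SoxB1 MO and 81.5% in the triple loss. First-wave genes at 2-fold were 83.0% in cycloheximide, 45.3% in U1U2 MO, 13.2% in SoxB1 MO, 28.3% in the library labelled MZpou5f1 and 28.3% in the rescue. With the minimum doubled they were 94.7% in amanitin, 15.8% in U1U2 MO, 89.5% in Nanog+SoxB1 MO, 15.8% in MZpou5f1 SoxB1 MO, 89.5% in the triple loss and 5.26% in the rescue.

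Intron shares at 2-fold were 96.2% in amanitin, 68.0% in cycloheximide, 54.0% in U1U2 MO, 22.7% in Nanog MO, 4.63% in SoxB1 MO, 29.4% in Nanog+SoxB1 MO, 8.39% in the library labelled MZpou5f1, 23.7% in MZpou5f1 Nanog MO, 14.9% in MZpou5f1 SoxB1 MO, 27.6% in the triple loss and 9.70% in the rescue. With the minimum doubled they were 43.1% in cycloheximide, 26.4% in Nanog MO, 0.41% in SoxB1 MO, 37.4% in Nanog+SoxB1 MO, 29.7% in MZpou5f1 Nanog MO, 11.4% in MZpou5f1 SoxB1 MO and 33.3% in the triple loss. A smaller pseudocount gave 96.4% in amanitin, 36.2% in cycloheximide and 28.8% in U1U2 MO, and a larger one 88.3%, 28.1% and 20.3%. Median-ratio scaling gave 38.05% in cycloheximide, 18.4% in Nanog MO, 25.05% in Nanog+SoxB1 MO, 21.03% in MZpou5f1 Nanog MO and 23.9% in the triple loss.

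Maternal genes retained at 6 hpf were, with a smaller pseudocount, 70.9% in amanitin, 93.7% in cycloheximide, 71.3% in Nanog MO, 68.6% in Nanog+SoxB1 MO, 19.8% in MZpou5f1, 55.6% in MZpou5f1 SoxB1 MO and 86.8% in MZpou5f1 Nanog+SoxB1 MO, and in the same order 62.3%, 90.3%, 58.6%, 54.7%, 8.29%, 40.2% and 78.8% with a larger one. Counted at 4-fold they were 34.2%, 66.3%, 17.1%, 16.6%, 0.56%, 5.37% and 37.4%. With the minimum doubled they were 94.3% in cycloheximide, 69.4% in Nanog MO, 64.8% in Nanog+SoxB1 MO, 50.6% in MZpou5f1 SoxB1 MO and 86.3% in MZpou5f1 Nanog+SoxB1 MO. Median-ratio scaling gave 62.3% in amanitin, 59.2% in Nanog+SoxB1 MO, 44.4% in MZpou5f1 SoxB1 MO and 80.4% in MZpou5f1 Nanog+SoxB1 MO. With the set picked from 1 WT library and compared with the other WT libraries, the means over the 3 turns were 65.1% in amanitin, 90.8% in cycloheximide, 63.2% in Nanog MO, 46.1% in MZpou5f1 SoxB1 MO and 80.5% in MZpou5f1 Nanog+SoxB1 MO. For shares of sets the cause was not tested beyond what a changed fold or set size gives by construction. The RPKM tables hold no counts, so the depth behind low values is unknown.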

Other observations

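In cycloheximide at 6 hpf, germ plasm genes lay above WT, with 8 of 10 higher by limma, 8 adjusted over the list alone, and buc at 4.84 ± 0.30 on the log2 scale (SE, 1 library against 3; adjusted p = 0.208 with an estimated correlation). The enveloping layer list had 14 of 17 genes lower and 2 higher, the same adjusted over the list alone (adjusted p = 0.208 with an estimated correlation). In MZpou5f1 SoxB1 MO at 6 hpf, 11 of 15 oocyte-derived genes were higher, 13 adjusted over the list alone (adjusted p = 0.255 with an estimated correlation).

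Footprints of other maternal transcription factors went both ways in Nanog+SoxB1 MO at the 64-cell stage, in 1 library per condition, and the genes given here were chosen after their values were seen. They were at 2593 RPM in WT and 3011 RPM in the morphants for ctnnb2, at 1792 and 2463 RPM for hmga1a, at 1285 and 1391 RPM for sall4, and at 647 and 400 RPM for ctcf (ratio 0.618, 95% interval 0.528 to 0.724). Input rose by more than footprints for ctnnb2, hmga1a and sall4. Footprints per input therefore fell for each gene given here, with log2 changes of -0.58 (ctnnb2), -0.26 (hmga1a), -0.61 (sall4) and -0.74 (ctcf). Some other factors of the list rose per input, such as stat3 (0.49) and ctnnb1 (0.13). In poly(A)+ RNA of WT at 4 hpf, mt-nd2, a mitochondrial gene, was at 776 RPKM against 20.2 RPKM in total RNA, and taf15 at 614 against 18.1 RPKM.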
